A study of Homo sapiens with 12 samples.

How the data were processed

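Gene expression was measured by paired-end RNA sequencing in 12 libraries from TC71, an established Ewing sarcoma cell line, in 4 groups of 3 replicates. Per the submitters' processing notes, STAR 2.7.2b, featureCounts 1.6.3, Subread 2.0.0 and DESeq2 1.24.0 were used with the GRCh37 (hg19) genome build; the notes give no order or settings, and strandedness is not given in the sources used here. The authors deposited, per the file headers, a table of log2(TPM + 1) values per library for each engineered line. TPM divides reads by gene length and scales each library to a total of 1000000. The authors also deposited, per the file headers, a results table for each line with a mean normalised count over the 6 libraries, a shrunken log2 fold change, a p-value and an adjusted p-value. The reference annotation used here is of another build, so no coordinates are given. Gene names, exonic lengths and GC content were taken from it, and these were found for 94.0% of the genes tested in the TRIM8 line and 90.9% of those tested in the EWS/FLI line.

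The treated columns of the TRIM8-line table carry a 2-letter code that the labels do not spell out. They were assigned to dTAGV-1 because it was the only other 24 h treatment in the series. Columns left out numbered 0. The tables hold 13542 genes for the TRIM8 line and 17510 for the EWS/FLI line, with 12726 gene symbols in common. For the TRIM8 line, 21 entries have names that start with a 5-digit number in place of a symbol and were not named. The gene numbers beside FKBP1A, BCL3 and RPL13 for the EWS/FLI line are not those usual for these symbols, so their values rest on the symbol alone. Reads of a transgene cannot be told from those of the gene it came from, and genes that share reads with close copies are uncertain.

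The gene lengths behind the deposited TPM values appear not to belong to their genes (see the closing section). A fold change within a gene does not depend on its length, apart from the filter, the pseudocount and the scaling of each library. Levels of different genes would depend on it, so levels are printed as RPM, the recovered reads of a gene per 1000000 recovered reads of its library. Whole reads were recovered from the deposited log2 values and the authors' deposited mean normalised count: 100.0% of values in each library lay within 0.05 of a whole number. On simulated tables this step returned 100.0% of the known counts for 13542 genes of the dTAGV-1 comparison and 17510 genes of the doxycycline comparison. Recovered reads over the listed rows came to 9635380 to 11827272 per library in the TRIM8 line and 41735195 to 65634895 in the EWS/FLI line.

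Each comparison was tested within its own table with limma 3.58.1 in R 4.3.3 (linear models with a moderated variance that follows a trend with expression, two-sided) on the deposited log2(TPM + 1) values. That trend runs over the mean of these values and, with lengths that appear wrong, need not follow read depth. The p-values therefore depend on the lengths too. Of the 131 genes called for dTAGV-1, 92 were also called with no variance trend. Genes with a TPM of at least 1 in at least 3 of 6 libraries were tested. Fold changes are on the log2(TPM + 1) scale, with a pseudocount of 1, which understates the change of genes with a low deposited TPM. As the lengths behind TPM appear not to belong to their genes, this shrinkage can differ between comparisons for the same gene. With doxycycline ICAM1 had 1.86 here against 5.08 in the authors' deposited table, and DUSP4 1.12 against 3.28. Sizes of change set against each other carry this limit. P-values were adjusted by the Benjamini-Hochberg method and a threshold of 0.05 was used. The difference between comparisons was tested with limma as an interaction over all 12 libraries. Fixed gene lists, 21 in number, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with the estimated correlation and fry beside it. The lists were EWS/FLI-activated, EWS/FLI-repressed, cell cycle, p53 targets, integrated stress response, NF-kB targets, type I interferon response, JAK-STAT feedback, hypoxia/HIF targets, cholesterol synthesis, immediate early, neural, mesenchymal and matrix, apoptosis, mitochondrially encoded, nuclear oxidative phosphorylation, VHL ligase and dTAG-related, ribosomal proteins, and blood, epithelial and endothelial markers. The design, the lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined.

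Named genes were the 4 targeted genes (TRIM8, FLI1, EWSR1 and FKBP1A) and, per direction, the 10 with the largest log2 fold change among genes past the threshold whose treated libraries all lay on one side of the controls and whose mean TPM reached 5 in either group. As the lengths behind TPM appear not to belong to their genes, this minimum does not keep out genes with few reads. Clone-based, antisense and pseudogene symbols were left out. Up to 3 members per list, and up to 5 genes per direction of the overlap and of the difference, were added. Some genes that meet these rules are not reported here.

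The limma step was tested on simulated data with 200 changed genes. Counts were drawn with the same spread for every gene of a comparison and with no library that stood apart. DMSO replicate 1 did stand apart, so the shares found are not the sensitivity on these data. For dTAGV-1, over 12862 genes, it found 95 of 100 genes changed by 1 on the log2 scale and 52 of 100 changed by 0.5, with 11 false calls among 158. For doxycycline, over 12999 genes, it found 99 and 91 of 100, with 18 false calls among 208. With no changed gene it called 0 in either simulation. The interaction step found 97 of 100 changed genes among 11446, with 5 false calls. There all changed genes moved by 1 on the log2 scale in the TRIM8 line only, with the same spread in both lines. Smaller differences were not simulated.

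Replicate libraries were compared before averaging. Chi-square per degree of freedom over genes ranged from 1.58 to 31.5 between replicates in the TRIM8 line and from 7.75 to 24.6 in the EWS/FLI line, so no pair looked like 1 library deposited again. In the TRIM8 line the replicate pairs with DMSO replicate 1 had 24.8 and 31.5, and all others 1.58 to 1.82. Nothing says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Alternatives covered the pseudocount, the filter, the scaling, the variance trend, a replicate block, each library left out, a fit of all 12 libraries, stricter thresholds and the authors' deposited table. Added after the data were seen were limma-voom on recovered reads, with and without library quality weights, TPM with annotated lengths, and removal of trends with length and GC content.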

Results

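Expression was profiled in 2 engineered versions of TC71, a cell line from Ewing sarcoma, a tumour driven by the fusion transcription factor EWS/FLI. The first line expressed TRIM8, a ubiquitin ligase, fused to the FKBP12F36V degradation tag. It received DMSO or dTAGV-1, a degrader that recruits the VHL ligase to the tag, for 24 h. The dTAGV-1 dose is not given in the sources used here. The second line carried a doxycycline-inducible EWS/FLI and received water or doxycycline at 500 ng/mL for 8 h. Each group had 3 replicates. Reads recovered over the listed genes numbered 9635380 to 11827272 per library in the first line and 41735195 to 65634895 in the second, so low genes were measured less precisely in the first. Levels below are RPM (reads per 1000000 reads of a library), mean ± SD, n = 3, and adjusted p-values are from limma unless stated.

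The targeted genes were examined first. TRIM8 mRNA was at 145 ± 23.1 RPM in DMSO and 158 ± 9.91 with dTAGV-1, a log2 fold change of 0.13 (SE 0.12, adjusted p = 0.653), and without DMSO replicate 1 the change was -0.0010. The degrader acts on the protein, so the mRNA does not check the labels. FLI1 and EWSR1, the fusion partners, differed by -0.07 and -0.04 on the log2 scale with dTAGV-1 (adjusted p = 0.701 and 0.801). FKBP1A, whose reads may include the tag, was at 336 ± 14.8 and 376 ± 9.58 (log2 fold change 0.16, adjusted p = 0.384); without DMSO replicate 1 it was 0.20 (adjusted p = 0.00311). With doxycycline, FLI1 rose from 64.4 ± 2.63 to 1158 ± 51.7, a log2 fold change of 4.15 (SE 0.06, adjusted p = 7.2e-10). EWSR1 rose from 371 ± 4.35 to 1280 ± 78.6, a log2 fold change of 1.79 (SE 0.06, adjusted p = 2.41e-07), and all 3 treated libraries lay above all controls for both genes. FKBP1A rose by 0.29 on the log2 scale (adjusted p = 0.00480), and TRIM8 was at 65.6 ± 5.38 and 65.3 ± 2.44 (adjusted p = 0.992).

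**Figure D1:**
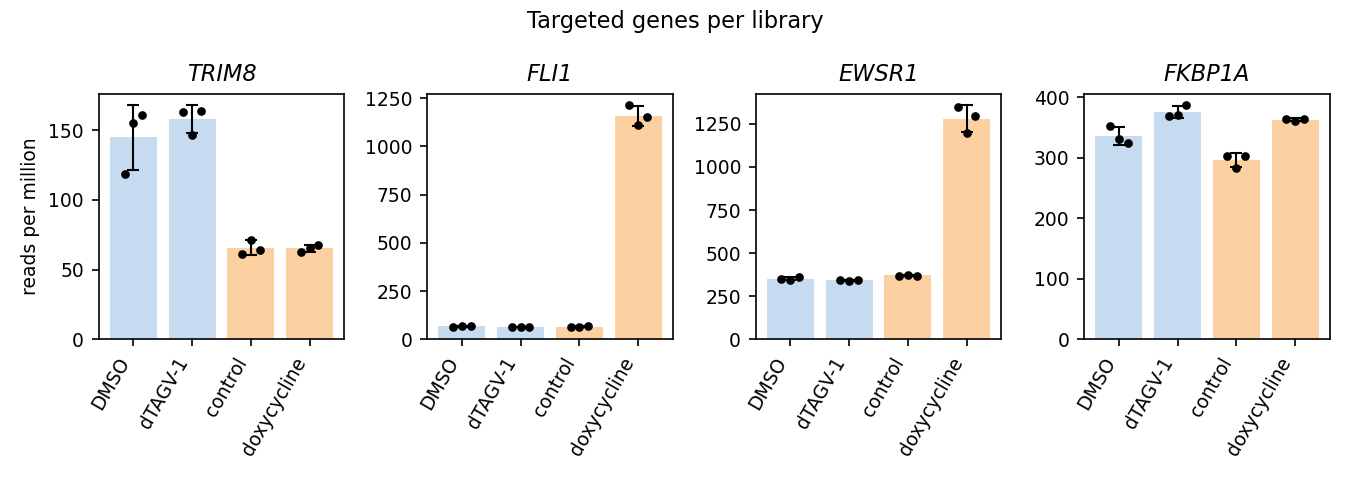
RPM of TRIM8, FLI1, EWSR1 and FKBP1A in the 4 groups; bars are means, error bars are SD and points are the 3 libraries of each group. FLI1 reached 1158 RPM with doxycycline against 64.4 in its control, while TRIM8 was at 145 with DMSO and 158 with dTAGV-1; the lines come from separate tables and levels between them were not tested.

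The first comparison asked what dTAGV-1 changed in the TRIM8 line. dTAGV-1 raised TGM2, a transglutaminase, from 6.27 ± 1.26 to 15.6 ± 0.815 RPM (2.36-fold on the scale of the test, adjusted p = 0.0161). It raised ISM2 from 25.8 ± 4.35 to 59.8 ± 0.713 (log2 fold change 1.19, SE 0.12, adjusted p = 0.0136) and TRNP1 from 57.5 ± 1.91 to 127 ± 6.91 (1.14, SE 0.07, adjusted p = 0.00691). SCG2, a neuroendocrine granin, fell from 17.1 ± 1.79 to 6.20 ± 1.47 (-1.39, SE 0.16, adjusted p = 0.0158), and DACT2 from 14.1 ± 0.527 to 6.19 ± 0.743 (-1.16, SE 0.10, adjusted p = 0.00822). TNS4, ST6GALNAC1, HTR6, AMER2 and TINCR also rose, by 1.38, 1.37, 1.28, 1.13 and 1.11 on the log2 scale, and SLC17A7, a vesicular glutamate transporter, from 28.2 ± 7.41 to 65.7 ± 2.38 RPM. DOK5, IGFBPL1, KRT25, the netrin receptor NEO1, the Notch target HEY1, SMOC2 and SERTM1 had log2 fold changes of -1.36, -1.06, -1.03, -0.98, -0.98, -0.96 and -0.93, and GAREM fell from 14.8 ± 1.87 to 7.32 ± 0.725 RPM. KRT25 rested on 6 to 20 reads per library, TNS4 on 9 to 43, DOK5 on 8 to 56, HTR6 on 14 to 67 and SMOC2 on 14 to 47. In the authors' deposited table KRT25 had a shrunken log2 fold change of -0.08 and no adjusted p.

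In all, 131 of 12865 tested genes passed the threshold, 108 higher and 23 lower, of which 14 and 6 changed by at least 1 on the log2 scale. The treated and control libraries did not overlap for 131 of these and for 23.3% of all tested genes, against 10% by chance. With limma the count was 1080 without DMSO replicate 1 (658 higher and 422 lower), 49 without DMSO replicate 3, and 0 without DMSO replicate 2 or any single dTAGV-1 library, where 1493, 983, 967 and 924 genes had an unadjusted p under 0.05 against 1595 with all 6 libraries. The authors' deposited table calls 495 genes, with 129 of the 131 among them.

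DMSO replicate 1 stood apart from the others: its Spearman correlation across genes with the other DMSO libraries was 0.983 and 0.981, against 0.996 between those. Its difference from them followed gene length (rho -0.55 across genes). Of the fixed lists, 6 passed camera in the dTAGV-1 comparison, and 0 with an estimated correlation. With fry, which asks whether a list moved one way, only the neural (adjusted p = 0.0139) and EWS/FLI-activated lists (0.0485) passed. Without any single library other than DMSO replicate 1 neither did (0.0564 to 0.117 and 0.0722 to 0.234). EWS/FLI-activated genes had a median log2 fold change of 0.20 (adjusted p = 0.00120; 0.323 with an estimated correlation), but only 1 of 37 tested members rose and 1 fell over all genes, with 16 and 3 adjusted over the list alone. The member that rose was NPY1R (0.67, SE 0.08, adjusted p = 0.0166) and the one that fell was CALCB (-0.69, SE 0.09, adjusted p = 0.0241). EWS/FLI-repressed genes had a median of -0.16 (adjusted p = 0.0267; 0.323 with an estimated correlation), with 0 of 14 called and 1 higher and 2 lower adjusted over the list alone. CDKN1A had -0.40, CYR61 -0.38 and ICAM1 0.75. That list lost its call without DMSO replicate 2 (adjusted p = 0.120), without DMSO replicate 3 (0.101) and with the length trend removed (0.0845). Neural genes had a median of -0.25 (adjusted p = 0.000740; 0.259 with an estimated correlation); 2 of 7 were called, NEUROD1 (-0.85, SE 0.12, adjusted p = 0.0304) and GAP43 (-0.80, SE 0.11, adjusted p = 0.0304), and 4 adjusted over the list alone.

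Cell cycle genes had a median of -0.04 (adjusted p = 0.0393; 0.856 with an estimated correlation) and 0 of 35 called, 0 adjusted over the list alone, with MKI67 at 0.42, CENPE at 0.35 and TOP2A at 0.34; the call was lost without DMSO replicate 2 (0.196), DMSO replicate 3 (0.214), dTAGV-1 replicate 1 (0.0572) or dTAGV-1 replicate 3 (0.102), with the length trend removed (0.193), with quantile normalization (0.111) and with the replicate block (0.0882). Nuclear oxidative phosphorylation genes had a median of -0.13 (adjusted p = 0.00290; 0.856 with an estimated correlation) and ribosomal protein genes -0.11 (adjusted p = 0.000740; 0.856 with an estimated correlation), with 0 called and 0 adjusted over the list alone in each. Without DMSO replicate 1 these medians were 0.03 (adjusted p = 0.908) and 0.04 (0.252). The first list also lost its call with the length trend removed (0.0845) and the second with quantile normalization (0.280), and both did with voom and quality weights (0.849 and 0.9897). Their members with the largest values included UQCRC1 (-0.25), ATP5O (-0.24), NDUFS8 (-0.23), RPS27A (-0.26) and RPL13 (-0.21).

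The remaining lists tested did not pass camera for dTAGV-1 (adjusted p from 0.682 to 0.988). BTG2 of the p53 targets (0.83, SE 0.07, adjusted p = 0.00822), VEGFA of the hypoxia targets (0.72, SE 0.09, adjusted p = 0.0189) and BMF of the apoptosis list (0.50, SE 0.09, adjusted p = 0.0486) rose. In the matrix list COL1A1 rose (0.90, SE 0.11, adjusted p = 0.0189) and VIM fell (-0.37, SE 0.06, adjusted p = 0.0439). Adjusted over the list alone, the counts higher and lower were 1 and 0 of 21 p53 targets, 2 and 0 of 19 hypoxia targets, 1 and 0 of 18 apoptosis genes, 5 and 5 of 21 matrix genes, and 4 and 1 of 15 immediate early genes. They were 1 and 0 of 9 NF-kB targets, 1 and 0 of 12 JAK-STAT genes, and 0 in each direction for 20 stress response, 18 interferon, 18 cholesterol and 7 VHL and dTAG genes. FOS (0.58), DUSP1 (0.42), KLF10 (0.40), BCL3 (0.61), SOCS3 (-0.33), SOCS2 (0.32), TNFAIP2 (0.40), IER3 (-0.33), OASL (0.42), OAS1 (0.40), OAS3 (0.31), STC2 (0.29), SESN2 (0.26), VLDLR (-0.24), SQLE (0.24), DHCR7 (0.23), SREBF2 (0.21), TCEB2 (-0.23) and FKBP1B (0.15) did not pass the threshold. The direction of the test, which is relative to other genes, was down while the median was above 0 for interferon (0.02) and VHL and dTAG genes (0.05), and while the mean was above 0 for stress response (0.02), NF-kB (0.05) and hypoxia genes (0.05). Mitochondrially encoded genes were not analysed here for this line. Among markers of other cell types, CD79A rose by 0.93, KRT8 by 0.63 and KRT18 by 0.58 on the log2 scale (adjusted p = 0.0225, 0.0148 and 0.0277); EGFL7 was at -0.39 and ESAM at 0.31, neither called. Adjusted over the list alone, 1 of 2 blood, 2 of 4 epithelial and 0 of 2 endothelial markers were higher. Summed epithelial markers went from 1381 ± 98.1 to 2085 ± 12.3 RPM, mostly KRT18, blood markers from 29.04 ± 2.13 to 49.2 ± 1.07 and endothelial markers from 36.9 ± 7.14 to 27.9 ± 1.71.

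The second comparison asked what induced EWS/FLI changed. NGFR, the p75 neurotrophin receptor, rose from 61.1 ± 5.66 to 728 ± 17.7 RPM (log2 fold change 3.54, SE 0.07, adjusted p = 9.91e-09). TGM2 rose from 3.37 ± 0.312 to 46.2 ± 0.394 (3.39, SE 0.07, adjusted p = 1.26e-08) and FUCA1, a lysosomal fucosidase, from 43.1 ± 3.23 to 405 ± 37.2 (3.19, SE 0.08, adjusted p = 4.29e-08). The kinase gene SGK1, ANGPTL4, complement C3, GNG12 and TFPI2 rose by 2.54, 2.52, 2.48, 2.43 and 2.41 on the log2 scale. ID1, an inhibitor of helix-loop-helix transcription factors, fell from 98.2 ± 5.76 to 34.9 ± 0.704 (-1.35, SE 0.07, adjusted p = 3.32e-06), and SAMD11 from 64.9 ± 1.6 to 23.3 ± 0.293 (-1.42, SE 0.05, adjusted p = 6.67e-07). KIAA1614, the kinase gene SIK1, HEYL, the sodium channel gene SCN7A, NEUROD1, SERTM1, FOXO6 and ATOH8 had log2 fold changes of -1.39, -1.34, -1.24, -1.17, -1.13, -1.11, -1.02 and -0.98.

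In all, 1954 of 13047 tested genes passed the threshold, 1270 higher and 684 lower, of which 150 and 10 changed by at least 1 on the log2 scale. The split depended on scaling: median-centring gave 982 higher and 999 lower, and quantile normalization 981 and 974. The count was 1148 without doxycycline replicate 1 and 1180 without doxycycline replicate 2, and the authors' deposited table calls 3376 genes.

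The mitochondrially encoded genes were the list that passed camera for doxycycline, and 0 passed with an estimated correlation. They had a median of -0.24 (adjusted p = 2.41e-05; 0.843 with an estimated correlation; fry adjusted p = 0.1001), with 4 of 11 lower, 9 adjusted over the list alone. The median was -0.15 without control replicate 1 and -0.36 without control replicate 3. MT-ND6 had -0.48 (SE 0.11, adjusted p = 0.0181), MT-ND5 -0.45 (SE 0.10, adjusted p = 0.0173) and MT-CO1 -0.40 (SE 0.09, adjusted p = 0.0127). The EWS/FLI-activated list had 8 of 36 members higher and 11 lower, 11 and 13 adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.168; fry adjusted p = 0.00735, down). CCK rose by 0.82 (adjusted p = 0.0102), while KDSR and LIPI had -0.72 and -0.62 (adjusted p = 2.22e-05 and 0.00244). Of 13 EWS/FLI-repressed genes 1 rose and 3 fell, 1 and 5 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0537). The camera test passed without control replicate 1 (0.0140). It also did without any single doxycycline library (0.00118 to 0.00859), but there the filter removed ICAM1, the only member that rose. ICAM1 rose from 0.245 ± 0.0503 to 8.65 ± 0.773 (1.86, SE 0.10, adjusted p = 5.96e-06), while CDKN1A and LOX fell by 0.57 and 0.57.

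Of 15 immediate early genes 6 rose and 3 fell, with DUSP4 at 1.12, DUSP1 at 1.08 and FOS at 0.97. Of 11 JAK-STAT genes 4 rose and 1 fell, with BCL3 at 1.17, SOCS3 at 0.86 and JAK1 at -0.51. Of 19 matrix genes 5 rose and 3 fell, with THY1 at 1.04, COL1A1 at 0.92 and ACTA2 at 0.62. Of 20 hypoxia targets 3 rose and 2 fell, with HK2 at -0.79 and VEGFA at 0.76. Of 21 p53 targets 3 rose and 4 fell, with ZMAT3 at -0.56 and TP53INP1 at 0.44. Of 17 interferon genes 3 rose and 1 fell, with IFITM1 at 0.97, IRF7 at 0.40 and IFI6 at 0.33. Of 19 apoptosis genes 3 rose and 2 fell, with BCL2L11 at 0.36 and BMF at -0.35. Of 35 cell cycle genes 1 rose and 2 fell, with CDC20 at 0.44, E2F2 at -0.47 and MCM6 at -0.19. Of 7 neural genes 1 rose and 2 fell, with NEFM at -0.31 and NEFL at 0.24. Of 18 cholesterol genes 2 fell, LSS at -0.39 and INSIG1 at -0.30. Of 20 stress response genes PPP1R15A rose (0.35), and of 29 ribosomal protein genes RPL13 rose (0.23); 0 of 26 oxidative phosphorylation genes were called, with SDHD at 0.21, NDUFA1 at 0.19 and COX5B at 0.18. Of 10 NF-kB targets 1 rose, ICAM1, and of 7 VHL and dTAG genes 1 rose, FKBP1A. None of these lists passed camera with all 6 libraries (adjusted p from 0.130 to 0.922). With fry the JAK-STAT, NF-kB and immediate early lists (adjusted p = 0.00686 each) and the interferon list (0.0193) passed upward and the neural list (0.00816) downward, with medians of 0.0093, 0.02, 0.16, 0.11 and -0.03. The NF-kB result did not hold without any single doxycycline library (0.495 to 0.926), where the filter removed ICAM1. The immediate early median was -0.02 without doxycycline replicate 1, and without doxycycline replicate 2 no list passed fry. Leaving out any single doxycycline library also made the filter remove DUSP4 (immediate early) and SOCS3 (JAK-STAT). Changes in these lists may thus come from the filter rather than from the library left out. Without control replicate 1 the ribosomal protein list (median 0.15, camera adjusted p = 0.00400) and the oxidative phosphorylation list (0.17, 0.00765) passed camera but not fry (0.115 and 0.144). Adjusted over the list alone, the counts higher and lower were 7 and 3 for immediate early, 4 and 1 for JAK-STAT, 8 and 5 for matrix, 3 and 2 for hypoxia, 3 and 4 for p53, 4 and 2 for interferon, 4 and 2 for apoptosis, 1 and 1 for cell cycle, 1 and 2 for neural, 0 and 2 for cholesterol, 1 and 0 for stress response, 2 and 1 for NF-kB, 2 and 0 for VHL and dTAG genes, and 0 and 0 for ribosomal protein and oxidative phosphorylation genes. The direction of the test was down while the median was above 0 for cell cycle (0.03), stress response (0.01), hypoxia (0.00052), cholesterol (0.02) and apoptosis genes (0.02). Of markers of other cell types, CD79A (1.28), KRT18 (0.59) and EGFL7 (0.69) rose. Adjusted over the list alone, 1 of 1 blood, 2 of 3 epithelial and 1 of 1 endothelial markers were higher. Summed blood markers went from 1.79 ± 0.436 to 6.86 ± 0.457 RPM, epithelial markers from 172 ± 5.86 to 243 ± 12.9 and endothelial markers from 22.9 ± 2.27 to 40.7 ± 3.76.

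**Figure D2:**
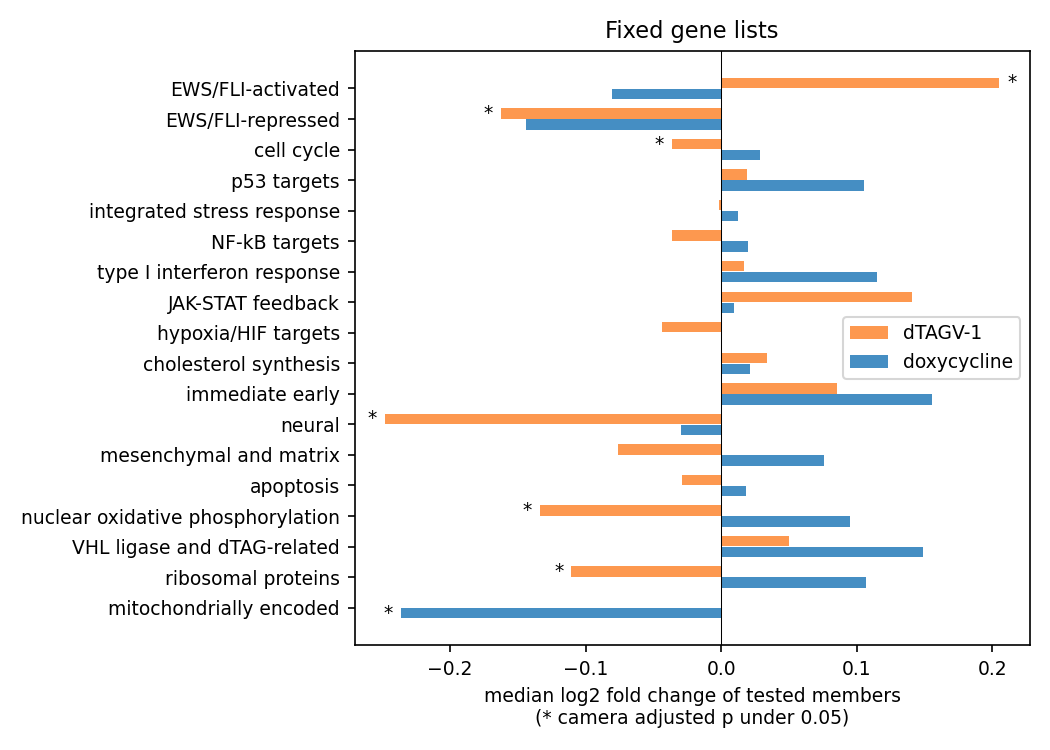
Median log2 fold change of the tested members of each fixed list with at least 5 tested members, for dTAGV-1 against DMSO and doxycycline against control; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The neural list was at -0.25 with dTAGV-1 and the mitochondrially encoded list at -0.24 with doxycycline, and 0 lists passed with an estimated correlation.

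The series title joins TRIM8 loss with EWS/FLI over-expression, so both responses were compared over the 11463 genes tested in both. The loss of TRIM8 protein itself is not measured by RNA sequencing. TGM2, ISM2, TRNP1, SGK1 and NGFR rose in both, SGK1 by 1.04 and 2.54 and NGFR by 1.03 and 3.54 on the log2 scale with dTAGV-1 and doxycycline. SERTM1, IGFBPL1, ID1, NEUROD1 and SCG2 fell in both, ID1 with -0.86 and -1.35 and SCG2 with -1.39 and -0.63. The change was larger with doxycycline in 44 of the 91 shared genes, and it differed between comparisons for 17, of which 16 changed more with doxycycline, all but DACT2. The pseudocount can lower a change unequally in the 2 comparisons, which limits these counts. So do the different lines, times (24 h and 8 h) and read depths. CD79A had 0.93 and 1.28 here, against 0.95 and 2.21 in the authors' deposited table. In all 78 genes rose in both, against 9.96 for independent lists, and 13 fell in both, against 1.16 (two-sided Fisher's exact test across genes, p = 5.72e-59 and 7.26e-12; genes are not independent replicates). Only 4 genes went in opposite directions, against 7.49. The 91 shared genes numbered 419 without DMSO replicate 1, 37 without DMSO replicate 3 and 0 without DMSO replicate 2 or any single dTAGV-1 library. Across genes, Pearson's r was 0.30 and Spearman's rho 0.17; 9 of the 100 pairs of splits of the libraries gave as large an absolute r, a permutation p of 0.09. Without DMSO replicate 1, r was 0.42 (permutation p = 0.01), and without control replicate 2 it was 0.33 (0.02). With any other library left out, r ranged from 0.22 (DMSO replicate 3) to 0.31 (doxycycline replicate 2). It was 0.23 without DMSO replicate 2.

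**Figure D3:**
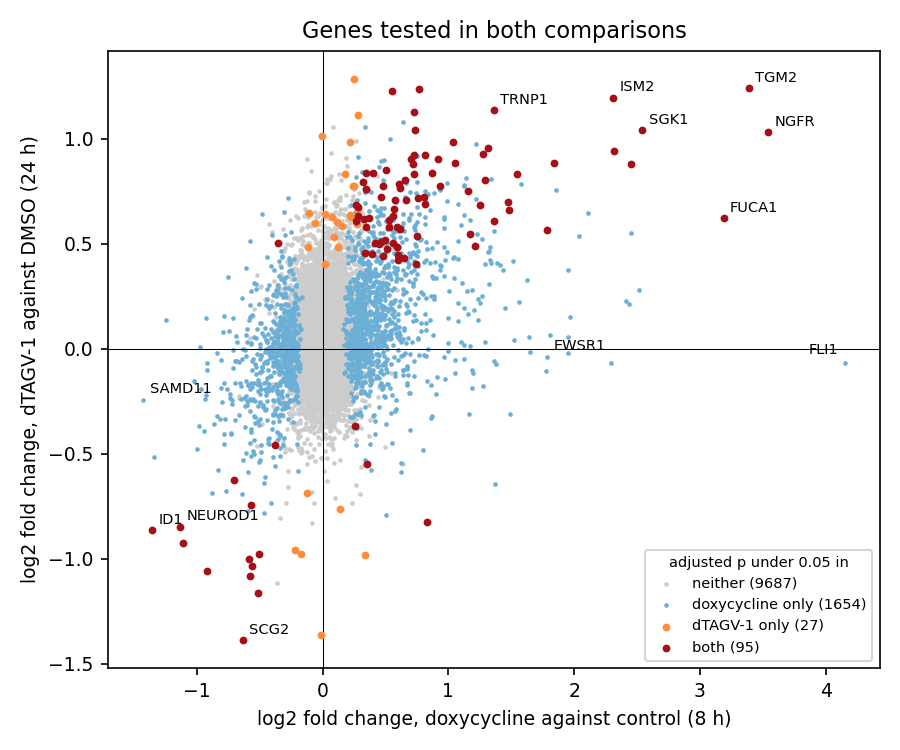
Log2 fold change with dTAGV-1 (vertical) against that with doxycycline (horizontal) for the 11463 genes tested in both, coloured by the comparison in which the limma adjusted p was under 0.05. Of the genes called in both, 78 lie in the upper right and 13 in the lower left, while FLI1 lies at 4.15 with doxycycline and -0.07 with dTAGV-1.

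The 200 genes with the highest moderated t for doxycycline had a median log2 fold change of 0.35 with dTAGV-1 (camera p = 6.51e-27; p = 0.00258 with an estimated correlation), and 82.5% were above 0 against 55.9% of all genes. The 200 lowest had a median of -0.10 (camera p = 3.11e-10; p = 0.242 with an estimated correlation), and without DMSO replicate 1 it was -0.21. The change itself differed between comparisons for 250 genes (limma interaction), 70 higher and 180 lower with dTAGV-1. The comparisons also differ in line, time (24 h and 8 h) and read depth, which cannot be told apart from the treatments here. FLI1, FUCA1, NGFR, NRTN and ANGPTL4 had differences of -4.22, -2.57, -2.51, -2.36 and -2.24, and HEYL, SAMD11, TRHDE, PDGFRB and IGF1 had 1.38, 1.18, 1.12, 1.09 and 1.09. The count was 685 without DMSO replicate 1, and 162, 151, 140 and 156 without control replicate 3 and doxycycline replicates 1, 2 and 3.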

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

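The limma-voom, annotated-length and trend-removal tests were chosen after the data were seen. The dTAGV-1 count of 131 stayed within 1.5 times under both pseudocounts, both filters, both scalings, no variance trend, voom (123), annotated lengths and GC-trend removal. The genes themselves held less well. Of the 131, 89 were called with annotated lengths, 92 with no variance trend, 101 with median-centring and 102 with voom. In the other settings just named 111 to 129 were. It was 1354 with voom and quality weights (808 higher and 546 lower), 283 with the length trend removed, 578 in the fit of all 12 libraries, 495 in the authors' deposited table, 20 at a log2 fold change of at least 1, 9 at an adjusted p under 0.01, and 0 to 1080 with a library left out. The doxycycline count of 1954 was 975 in the fit of all 12 libraries, 3376 in the authors' deposited table, 160 at a log2 fold change of at least 1, 1016 at an adjusted p under 0.01, and 1148 to 2162 with a library left out; voom gave 2253, with 1698 genes shared.

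Replicate numbers did not pair the libraries: same-number deviations correlated from -0.06 to 0.03 in the TRIM8 line and from -0.18 to -0.05 in the EWS/FLI line, and best matches lay elsewhere. With the number as a replicate block the counts were 0 and 1374, the shared genes 0 and the differing genes 158.

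Shared genes were 570 with quality weights, 168 with the length trend removed and 0 to 419 with a library left out; differing genes were 926, 419 and 140 to 685. The correlation passed its split test with voom (0.29), quality weights (0.34) and the length trend removed (0.35), and ranged from 0.22 to 0.42 with a library left out. The doxycycline-down result was -0.10 at p = 0.242 with an estimated correlation. Lists passing for dTAGV-1 were 3 with the length trend removed and 0 with an estimated correlation; for doxycycline they were 2 with quantile normalization, 0 with an estimated correlation and 1 to 4 with a library left out. The fry calls for dTAGV-1 were lost with the replicate block (0.195 for both lists) and annotated lengths (0.0675 for neural, 0.151 for EWS/FLI-activated genes). Those for doxycycline were all lost with the replicate block (0.0612 to 0.147) and without doxycycline replicate 2 (0.0575 to 0.926), all but the EWS/FLI-activated list with quality weights (0.0602 to 0.0983), and for interferon genes without any library but control replicate 3 (0.0553 to 0.0929). Further losses were interferon genes with quantile normalization (0.0738), EWS/FLI-activated genes with annotated lengths (0.147), immediate early genes with voom (0.0555), NF-kB targets without doxycycline replicates 1 or 3 (0.785 and 0.495), and neural genes with no filter (0.0582), voom (0.0893) or without doxycycline replicate 1 (0.0593). Without any single doxycycline library the filter removed ICAM1, DUSP4 and SOCS3, so losses of the NF-kB, immediate early and JAK-STAT lists there may come from the filter. For dTAGV-1 the EWS/FLI-activated list also lost its call with no filter (0.0516). The lowest depth, in the TRIM8 line, limits what low genes such as KRT25 can show.

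TRIM8 with doxycycline, at 0.0015 on the log2 scale and not called, reversed with quantile normalization (-0.0166), median-centring (-0.0429), voom (-0.0340), quality weights (-0.00561), annotated lengths (-0.00146), the length trend removed (-0.00412) or the GC trend removed (-0.0785), in the authors' deposited table (-0.0331), and within -0.0481 to 0.0642 with a library left out. TRIM8 with dTAGV-1 ranged from -0.00104 to 0.214 with a library left out, and EWSR1 with dTAGV-1 was 0.00492 with annotated lengths. FKBP1A with dTAGV-1 was called with quality weights (0.186) and ranged from 0.133 to 0.198 with a library left out. Also reversed, without a call, were NRTN with dTAGV-1 (0.0845 with quality weights, 0.00887 with the GC trend removed, -0.244 to 0.180 with a library left out), HEYL with dTAGV-1 (-0.0222 to 0.290), and SDHD (-0.0146 to 0.353) and NDUFA1 (-0.0499 to 0.451) with doxycycline.

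List directions, taken from camera, reversed as follows, with medians. For dTAGV-1, VHL and dTAG genes were at 0.00423 with quantile normalization, 0.0750 with quality weights, 0.0963 with annotated lengths, 0.0195 with the length trend and 0.00521 with the GC trend removed, and -0.0332 to 0.0840 with a library left out. Ribosomal protein genes were at 0.0159 with quality weights and -0.185 to 0.0374 with a library left out, and oxidative phosphorylation genes at -0.193 to 0.0279. Stress response genes were at 0.0407 with annotated lengths, 0.0330 with the length trend removed and -0.0188 to 0.0384 with a library left out. Interferon genes were at 0.0216 with the length trend removed and -0.00507 to 0.0320 with a library left out, NF-kB targets at -0.0746 with the GC trend removed, JAK-STAT genes at -0.0179 to 0.213 and hypoxia targets at -0.0641 to -0.0166 with a library left out. For doxycycline, hypoxia targets were at -0.0153 with quantile normalization and -0.0150 to 0.0605 with a library left out, stress response genes at -0.0326 to 0.0908, NF-kB targets at -0.0434 to 0.0456 and oxidative phosphorylation genes at 0.0225 to 0.166. The cause of these changes was not tested. Of the genes picked by the naming rules and called, besides the targets, 36 for dTAGV-1 and 67 for doxycycline, 30 and 65 were called with voom, 35 and 67 in the authors' deposited table, and 0 and 63 with the replicate block; 0 changed sign.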

Other observations

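The gene families below and all explanations were tested after the result was seen. Families taken by gene symbol, 7 in each comparison and 14 tests in all, were tested with fry, which asks whether a family moved one way, and with camera beside it. The adjusted p-values cover these 14 tests but not the choice of families. Members such as ID1 and HEYL were already named above, so these p-values are not independent support. With doxycycline the ID genes fell (median log2 fold change -0.71, fry adjusted p = 0.000777), with ID1 at -1.35, ID4 at -0.79 and ID3 at -0.63 called and ID2 at 0.09 not called. HES and HEY genes, many of them Notch targets, fell (median -0.31, 0.00123), with 4 of 6 called, HEYL at -1.24 and HEY1 at -0.50 among them. Semaphorins rose (0.19, 0.00187), with 7 of 14 higher and 1 lower, SEMA3F at 1.37 and SEMA3A at -0.83. Eph receptors and ephrins had 5 of 16 higher and 2 lower (0.14, 0.000687), with EPHA2 at 2.31, EFNA1 at 1.97 and EPHA4 at -0.97. Collagens had 1 of 23 higher and 5 lower (-0.14, 0.0324). These medians kept their sign with quantile normalization, at -0.71, -0.35, 0.12, 0.08 and -0.20. With camera the Eph receptors and ephrins did not pass (adjusted p = 0.0504), while the other families named in this paragraph did (0.000488 to 0.0200).

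With dTAGV-1 EPHA2 and EPHB3 rose by 0.94 and 0.80 (adjusted p = 0.0118 and 0.00822). The family median was 0.15 (fry adjusted p = 0.0462, camera adjusted p = 0.0392). ID genes had a median of -0.23 (fry adjusted p = 0.154) and HES and HEY genes -0.11 (0.0774). Without DMSO replicate 1 their unadjusted fry p was 0.00381 and 0.0177, against 0.121 and 0.0498 with all libraries. Collagens, semaphorins and potassium channels did not pass (0.958, 0.958 and 0.389), nor did potassium channels with doxycycline (0.120). Dual specificity phosphatases passed fry in both comparisons (0.0358 and 0.00364) but not camera (adjusted p = 0.436 and 0.375). Their medians of 0.03 and 0.05 changed sign with quantile normalization, at -0.03 and -0.0074. Without DMSO replicate 1 their unadjusted fry p with dTAGV-1 was 0.0735, against 0.0179 with all libraries.

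Other splits of the libraries gave these results. The 3 against 3 libraries of a line make 10 splits, too few for a share under 0.1. The real split called 131 genes for dTAGV-1 and 1954 for doxycycline, as 1 of 10 in each, and the highest other called 0. For lists, 1 of 10 splits gave as many as the 6 for dTAGV-1 (highest other 3) and 9 of 10 as many as the 1 for doxycycline (highest other 6). The doxycycline-up genes had the largest median in 1 of 10 splits (0.35, highest other 0.143), and 4 of 10 gave as large a median for the doxycycline-down genes (-0.10, highest other 0.169). Over 100 pairs of splits, 1 gave as many as the 91 shared genes (highest other 0), which decides nothing, since no other split of either line called a gene. For the 250 differing genes 4 of 100 pairs gave as many (highest other 465). That share is under 0.05, without adjustment for the other split tests. All 4 pairs held the real doxycycline split, so chance in the TRIM8 line was not excluded. Nor was chance excluded for the correlation, where 9 of 100 were as large as 0.30 (highest other 0.362).

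DMSO replicate 1 differed from the other libraries of its table. A low depth is argued against by its reads, 11.8 in units of 1000000, against a median of 10.5 in the others. A trend with transcript length may account for part of the difference: its log2 difference from the other DMSO libraries had a rho of -0.55 with exonic length across genes, against at most 0.0912 in size within the dTAGV-1 libraries. DMSO replicates 2 and 3 had 0.447 and 0.513, each set against libraries that included replicate 1. This rho alone therefore does not single out replicate 1. The shortest genes of replicate 1 lay at 0.41 and its longest at -0.41. Whether the length trend came from RNA quality, library preparation or the cells was not tested.

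Deposited TPM of the same genes correlated less between the tables than reads did. Different expression in the engineered lines is argued against, since control RPM, as defined for the report, had a rho of 0.916 between tables across genes, against 0.733 for TPM. Lengths belonging to other genes may be the source: the length implied by TPM and reads had a rho of -0.0112 with annotated exonic length in the TRIM8-line table and -0.0174 in the EWS/FLI-line table. With annotated lengths the rho between tables was 0.915.

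The genes shared by dTAGV-1 and doxycycline were weighed against trends within libraries. With the length trend removed r was 0.351, and with the GC trend removed it was 0.314, against 0.299 before, which argues against either trend as the whole source. One hypothesis is more EWS/FLI output in both lines. The list of known activated targets had a median of -0.0807 under doxycycline, against 0.20 with dTAGV-1. Under doxycycline camera did not call it and fry did, downward (adjusted p = 0.00735, lost in some settings), with 8 members higher and 11 lower. As the list did not rise where FLI1 and EWSR1 mRNA rose by 4.15 and 1.79, it cannot decide on the hypothesis. The 200 doxycycline-up genes had a median of 0.35 with dTAGV-1 and the 200 doxycycline-down genes -0.10. Their camera p was 0.00258 and 0.242 with an estimated correlation. A rise of the first goes with the hypothesis but does not exclude another shared cause. No line without the tag or the transgene was analysed here, so effects of dTAGV-1 or doxycycline themselves cannot be told apart from those of their targets.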
